A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

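The data were 4 2-colour arrays that compared RNA of Congo red-treated and untreated BY4741 cells. Per the labels, an overnight culture was diluted, grown at 24 °C and divided, and 1 part received 30 µg/ml Congo red while the other did not. Both parts were sampled after 2 h, and total RNA was taken. Groups and array numbers came from the labels, which give the channel of each RNA but name no dye, ratio direction or method of analysis. The deposited values are log2 ratios per spot, which was read from the values themselves: they are signed, and their highest value corresponds to a ratio of 1e+05. Scanner settings, background correction, normalization within arrays and ratio direction are not given in the sources used here. Deposited array medians were 0.31, 0.02, -0.46 and 0.37 on arrays 1 to 4, so the values were not centred on 0. Median absolute deviations were 0.60, 0.61, 0.52 and 0.40. Blank cells made up 6.79%, 9.30%, 3.93% and 1.67% of the 12800 spots. At the upper limit lay 36 spots, 29 on array 3 and 7 on array 4, and these were kept. Signal strengths were not used here, so no spot could be judged against its background. Whether a normalization within arrays had been applied stays unknown.

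Spots were named through the platform's gene annotation, which is old. It gave 1 gene symbol for 11138 spots, several for 0 and none for 1662, which are unnamed here and were left out of the gene tests. Symbols were looked up by gene number in the RefSeq gene table of the yeast reference, which held 11128 of the named spots and lacked 10, and 0 symbols changed. Most genes, 5510 of 5539, were printed as 2 spots, with 28 as 4 spots and 1 as 6. The spots of a gene were averaged on each array. Adjacent spots of 1 gene had a Spearman's rho of 0.75, 0.50, 0.68 and 0.67 on arrays 1 to 4, and 9.51%, 18.0%, 8.89% and 5.94% of these pairs lay more than 1 log2 unit apart. No coordinates are printed, since no genome build is named for the array.

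Each array was centred on its median, and genes with values on at least 3 arrays were tested with limma 3.58.1 in R 4.3.3. The model held the mean log2 ratio alone (lmFit and eBayes, two-sided, against 0), with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors printed as SE are limma's moderated standard errors. The 4 arrays entered as replicates because the labels do not say whether they are separate cultures or repeats. The design, the alternatives, the 28 gene lists and the rule for named genes were fixed before the data were examined.

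Gene lists with at least 3 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01. Camera cannot take missing values, so its preranked form was run on the moderated statistics turned into z values, which departs from the plan. Camera with an estimated correlation and fry, another limma test, were run on the genes with values on all 4 arrays. Beside each list stand the members past the threshold over all genes and those adjusted over the list alone. The lists were the Slt2-Rlm1 markers, cell wall integrity signalling, glucan, chitin, mannoproteins, yapsins, protein mannosylation, Msn2/4 stress, HOG, calcineurin-Crz1, heat shock, unfolded protein response, ribosomal proteins, ribosome biogenesis, glycolysis, TCA cycle, amino acids, ergosterol, cell separation, G1/S, histones, G2/M, pheromone and a-cell, alpha-cell, meiosis, iron, phosphate and the deleted genes. Some genes stand in more than 1 list. The ribosomal list was built from a name pattern, which took in RPP1 by mistake.

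The named genes were, in each direction, up to 10 past the threshold with the largest mean and 1 sign on all 4 arrays, filled up to 5 by unadjusted p where fewer passed. The 8 markers, the deleted genes and the members of each list with the smallest p were added, up to 4 for a list past the threshold and up to 2 for the others. Other names were chosen after their values were seen, and the text says so.

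The direction rule took the mean Pearson correlation between arrays of opposite channel assignment. A value beyond 0.3 on either side of 0 would have settled whether the ratios run by treatment or by channel, and a value between leaves it open. The sign was then called likely from the marker genes, by the 95% interval of their mean over genes. For that reason, lists that hold markers were also tested without them.

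Alternatives were no centring, scaling to a common median absolute deviation, quantile normalization, a channel term, arrays averaged in pairs, genes with values on all 4 or at least 2 arrays, single spots, robust eBayes, a test against a fold change of 1.5, each array left out, an estimated correlation, fry, and lists without markers. Added after the data were seen were leaving out values at the upper limit, centring within runs of 400 spot numbers, leaving out spot pairs more than 1 log2 unit apart, turning the sign of arrays 2 and 4, the ribosomal list without RPP1, and camera itself with the preset correlation on genes with values on all 4 arrays.

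The limma steps were tested on simulated data for this comparison, with 5489 genes and 50 changed genes at each size. The test recovered 16% of genes changed by a log2 ratio of 1, 72% at 2, 88% at 3 and 92% at 4. It called 138 genes, of which 4 were unchanged. The shifted list was found (camera adjusted p = 5.30e-10), and 0 of 27 other lists were called. Noise was drawn independently for each gene, whereas the data gave estimated correlations within lists of up to 0.93, for histones. The count of 0 thus does not show how rarely camera calls an unshifted list in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.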

Results

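Transcript levels of the budding yeast Saccharomyces cerevisiae were compared between cells grown with Congo red for 2 h and cells of the same divided culture that grew on without it. Congo red is a dye that binds cell wall polysaccharides and disturbs wall assembly. It was used at 30 µg/ml, in rich medium at 24 °C. The strain was BY4741, a haploid laboratory strain of mating type a with deletions in HIS3, LEU2, MET17 and URA3. The data were 4 2-colour microarrays of 1 group, numbered 1 to 4, and each array held treated and untreated RNA. Treated RNA was in channel 2 on arrays 1 and 3 and in channel 1 on arrays 2 and 4. The labels do not say whether the arrays carry RNA of separate cultures, so p-values measure only the spread between these arrays, which may be technical. Of 12800 spots, 11931, 11609, 12297 and 12586 had a value on arrays 1 to 4. Gene symbols were given for 11138 spots, which covered 5539 genes. The 5489 genes with values on at least 3 arrays were tested, and the small number of arrays limits the precision. All values below are log2 ratios with the array median at 0, read as Congo red over untreated. That direction is likely but not settled, on the basis given with the comparison of the channel assignments.

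Transcripts of 5 genes rose with Congo red in the limma test, and all 5 were above 0 on each of the 4 arrays. CRG1 (YHR209W), a methyltransferase that uses S-adenosylmethionine, had the highest mean at 3.50 ± 0.20 (SE, n = 4), which is 11.3-fold, with a limma adjusted p = 0.036. NCW2 (YLR194C), a cell wall protein with a lipid anchor, was at 3.04 ± 0.18 or 8.22-fold (limma adjusted p = 0.036). SRL3 (YKR091W), also called WHI7 and known to restrain the start of the cell cycle, was at 2.40 ± 0.17 or 5.29-fold. GFA1, which encodes the first enzyme of the route to the chitin precursor, was at 2.06 ± 0.15 or 4.17-fold. PST1, another lipid-anchored cell wall protein, was at 1.95 ± 0.14 or 3.85-fold. The limma adjusted p was 0.045 for each of SRL3, GFA1 and PST1. In arrays 1 and 3 the means of the 5 genes ran from 1.82 for PST1 to 3.83 for CRG1, and in arrays 2 and 4 from 1.97 for GFA1 to 3.31 for NCW2. GFA1 was lower on array 2, at 1.77, than on the other arrays, where it was at least 2.13. NCW2 and PST1 are among the marker genes used to read the direction, so their sign is not independent evidence of it.

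No gene passed the limma threshold below 0. At an unadjusted p under 0.05 there were 425 genes, 295 higher and 130 lower, where chance alone gives 274. The lower genes with the smallest p and 1 sign on all arrays were PHO12 at -1.13 ± 0.13 (SE, n = 4), PHO11 at -1.03 ± 0.13, RRT5 at -0.93 ± 0.15, PGA3 at -0.90 ± 0.17 and PHO5 at -0.83 ± 0.15, with limma adjusted p from 0.16 to 0.31. The 5 calls above 0 were lost when any 1 of the arrays was left out (0 genes each time, 222 to 484 at an unadjusted p under 0.05, smallest limma adjusted p from 0.13 to 0.29). They were also lost with a term for the channel assignment (smallest limma adjusted p = 0.054), with arrays scaled to a common spread (0.19), with quantile normalization (0.39), with arrays averaged in pairs (0.41 and 0.44), with each array centred along the spot order (0.060) and in a test against a fold change of 1.5 (0.059). The means of the 5 genes stayed about as large or larger in the settings that could move them. CRG1 was at 3.52 ± 0.26 (SE, n = 4) with scaling and 4.13 ± 0.76 with quantile normalization. The channel term, the pair averages and the fold change test leave the mean of these genes unchanged by design. The mean of CRG1 with the channel term, 3.50 ± 0.12, is thus no sign of stability. Without median centring PST1 alone of the 5 lost its call (limma adjusted p = 0.065), and CWP1 and YPL088W passed (0.026 and 0.016).

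**Figure D1:**
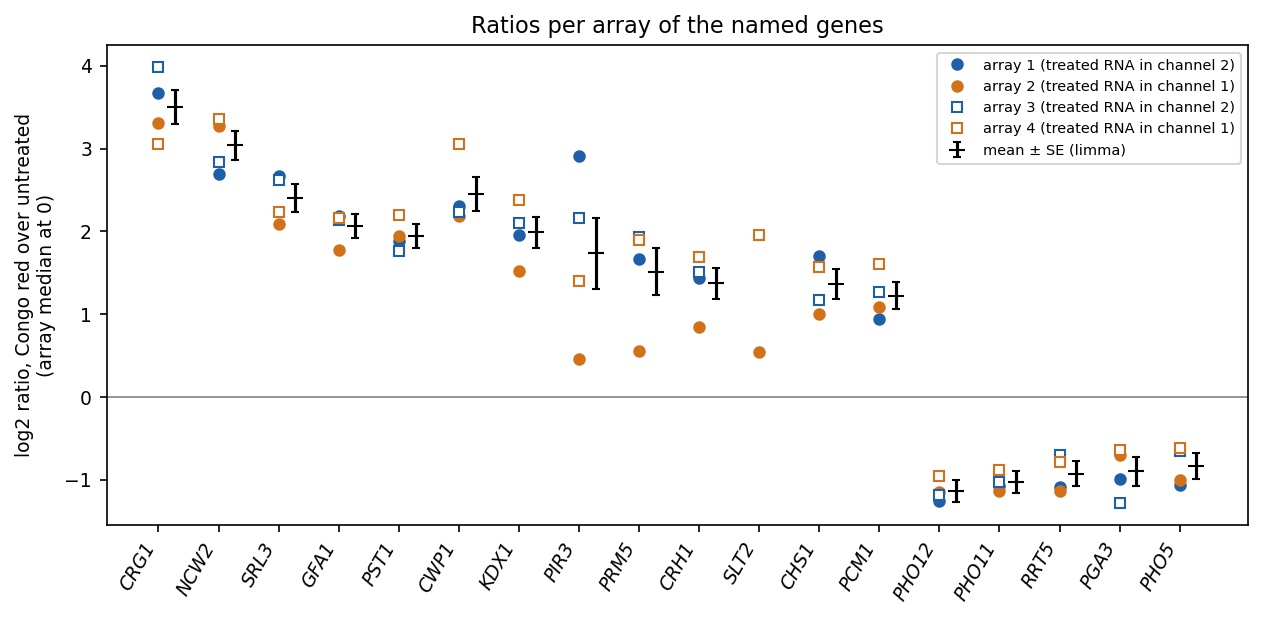
Log2 ratio of Congo red over untreated (vertical axis, array median at 0) for 18 named genes (horizontal axis), with 1 symbol per array and the limma mean ± SE beside it where a gene had values on at least 3 arrays. Blue marks arrays 1 and 3 and orange marks arrays 2 and 4. CRG1 lies between 3.06 and 3.98 and NCW2 between 2.69 and 3.35, while SLT2 has values on arrays 2 and 4 alone, at 0.55 and 1.95.

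The marker genes of the Slt2-Rlm1 route, the kinase and transcription factor of cell wall stress, stood highest among the gene lists. Of 7 tested members, NCW2 and PST1 passed the threshold over all genes and 5 did not, while 7 passed when adjusted over the list alone. The list median was 1.95, with array medians of 1.96, 1.52, 2.11 and 2.19 (camera adjusted p = 3.95e-14, and adjusted p = 0.17 with an estimated correlation). CWP1, a mannoprotein of the wall, was at 2.45 ± 0.20 (SE, n = 4, limma adjusted p = 0.062), and KDX1, a kinase related to Slt2, was at 1.99 ± 0.19 (limma adjusted p = 0.090). CWP1 stood higher on array 4, at 3.06, than on the others, where it was at most 2.31. PIR3, PRM5 and CRH1 were at 1.73 ± 0.43, 1.51 ± 0.28 and 1.37 ± 0.19. SLT2 itself was measured on arrays 2 and 4 only, at 0.55 and 1.95. This list sets the reading of the direction and is no independent evidence of it.

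Signalling genes of the cell wall integrity pathway were above the other genes as a list, though none of the 25 tested members passed over all genes. The list median was 0.08 (camera adjusted p = 0.0066, and adjusted p = 0.42 with an estimated correlation). In the mean 15 members were above 0 and 10 below, so the list did not rise as a whole. Members below 0, singled out after their values were seen, included PKC1 at -0.24 ± 0.32 and SLG1 at -0.35 ± 0.53. Adjusted over the list alone, 3 passed: KDX1, PTP2 at 1.59 ± 0.24 (SE, n = 4) and MSG5 at 0.90 ± 0.15. PTP2 and MSG5 encode phosphatases that act on MAP kinases. LRG1, which acts on the GTPase Rho1, was at 0.97 ± 0.27. Array medians were 0.33, -0.03, 0.33 and 0.10. Without array 3 the median was 0.04 and the camera call was lost (adjusted p = 0.056). The fry test, which asks whether the genes of a set move on balance one way, gave an adjusted p = 0.19.

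Genes of chitin synthesis and remodelling lay above the other genes, with 15 of 20 tested members above 0 in the mean. The list median was 0.27 (camera adjusted p = 0.00012, and adjusted p = 0.17 with an estimated correlation). GFA1 passed over all genes, 19 members did not, and 6 passed when adjusted over the list alone. Among these, CHS1, a chitin synthase used at cell separation, was at 1.36 ± 0.18 (SE, n = 4, limma adjusted p = 0.17). PCM1, a mutase of N-acetylglucosamine phosphate, was at 1.22 ± 0.17 (0.18), and the wall transglycosylase CRH1 was at 1.37 ± 0.19 (0.18). Members singled out after their values were seen were CHS3, the synthase of most wall chitin, at 0.31 ± 0.18, and GNA1 and QRI1, the other enzymes of the precursor route, at -0.38 ± 0.28 and 0.03 ± 0.19.

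Glucan synthesis and remodelling genes had a list median of 0.18, with 20 of 30 tested members above 0 in the mean (camera adjusted p = 0.0027, and adjusted p = 0.17 with an estimated correlation). No member passed over all genes, and 0 passed when adjusted over the list alone. FKS1, a catalytic subunit of glucan synthase, was at 0.96 ± 0.20 (SE, n = 4), the glucanase gene BGL2 was at 0.80 ± 0.18 and KNH1 at 0.89 ± 0.21. Cell wall mannoproteins had a median of 0.20. Of 34 tested members, NCW2 and PST1 passed over all genes, 32 did not, and 8 passed when adjusted over the list alone. AFB1, a secreted barrier factor, was at 1.24 ± 0.16 (limma adjusted p = 0.17). The camera adjusted p of this list was 0.0017, and its adjusted p = 0.42 with an estimated correlation. Without the marker genes its median was 0.03 and the call was lost (adjusted p = 0.15), as it was without array 4 (median 0.08, adjusted p = 0.0505).

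Calcineurin-Crz1 targets, the genes of a calcium-dependent stress route, had nearly equal list medians of 0.57, 0.61, 0.58 and 0.60 on arrays 1 to 4. None of the 13 tested members passed over all genes, and 6 passed when adjusted over the list alone (camera adjusted p = 2.79e-05, and adjusted p = 0.17 with an estimated correlation). RCN1, a regulator of calcineurin, was at 1.44 ± 0.23 (SE, n = 4), and the calmodulin-dependent kinase gene CMK2 was at 1.15 ± 0.24. CHS1 and the protease gene YPS1, at 1.04 ± 0.17, belong to this list too. Yapsins, aspartyl proteases at the cell surface, had a list median of 0.66 over 6 members (camera adjusted p = 0.029, and adjusted p = 0.52 with an estimated correlation). Their array medians were 1.33, 0.34, 0.83 and 0.11, higher on arrays 1 and 3 than on arrays 2 and 4. None passed over all genes and 2 passed when adjusted over the list alone, YPS1 and YPS3 at 1.46 ± 0.21. YPS6 varied widely, at 6.74, 1.88 and 0.18 on arrays 1, 2 and 4, and MKC7 was at -0.25 ± 0.16. The yapsin call was lost without array 2 (median 0.57, adjusted p = 0.072) and without array 4 (median 0.46, adjusted p = 0.23), and fry gave an adjusted p = 0.092. It was also lost with genes valued on all 4 arrays, which leaves out YPS6 and YPS5 (median 0.49, adjusted p = 0.082), and without spot pairs more than 1 apart (adjusted p = 0.084).

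The HOG pathway and osmostress list and the unfolded protein response list had small shifts above 0, and no member of either passed over all genes or when adjusted over the list alone. The HOG list, of the route that answers high osmolarity, had a median of 0.20 over 22 tested members (camera adjusted p = 0.0066, and adjusted p = 0.17 with an estimated correlation). Its members with the smallest p were SSK22 at 0.58 ± 0.13 (SE, n = 4), MSB2 at 0.56 ± 0.16 and GPD1, of glycerol synthesis, at 0.37 ± 0.13. In the mean 15 members were above 0 and 7 below. Among the lower ones was STL1 at -0.32 ± 0.18, singled out after its value was seen. Unfolded protein response genes had a median of 0.25 over 15 tested members (camera adjusted p = 0.034, and adjusted p = 0.31 with an estimated correlation). ERO1, an oxidase of the endoplasmic reticulum, was at 0.75 ± 0.30, and HAC1, the transcription factor of this response, was at 0.63 ± 0.31. Both calls were lost without median centring (adjusted p = 0.12 each). The unfolded protein call was also lost without array 4 (median 0.18, adjusted p = 0.091), without spot pairs more than 1 apart (median 0.25, adjusted p = 0.056) and by fry (adjusted p = 0.14).

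The phosphate regulon lay below the other genes, with a median of -0.33 and array medians of -0.40, -0.18, -0.35 and -0.28 (camera adjusted p = 0.0021, and adjusted p = 0.31 with an estimated correlation). None of its 16 members passed over all genes, and 3 were lower when adjusted over the list alone: PHO12, PHO11 and PHO5, which encode secreted acid phosphatases. These 3 genes are close relatives, and PHO11 and PHO12 are nearly identical, so their spots may share signal and their values are uncertain. PHO8, a phosphatase of the vacuole, was at -0.53 ± 0.15 (SE, n = 4). SPL2, singled out after its value was seen, went the other way at 1.02 ± 0.29.

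Cytosolic ribosomal protein genes split by channel assignment. Their list median was -0.78 on array 1 and -0.63 on array 3, but 0.14 on array 2 and 0.15 on array 4. Over the 4 arrays the median was -0.29, with 128 of 133 tested members below 0 in the mean and 15 below 0 on all arrays (camera adjusted p = 3.35e-12, and adjusted p = 0.52 with an estimated correlation). Across the alternative settings the median ran from -0.43 to -0.13. No member passed over all genes or when adjusted over the list alone, and fry gave an adjusted p = 0.40. RPS0A was at -0.51 ± 0.13 (SE, n = 4), RPS0B at -0.43 ± 0.13 and RPL3 at -0.45 ± 0.16. These genes were named for their small p and are among the 15 below 0 on all arrays, so they do not show the split of the list. The name pattern of this list also took in RPP1, a subunit of ribonuclease P that is not ribosomal, at -0.58 ± 0.21. Histone genes split likewise, with array medians of -1.04, -0.09, -0.75 and -0.01. All 10 were below 0 in the mean, led by HTB1 at -0.62 ± 0.23, HHT1 at -0.59 ± 0.24 and HTB2 at -0.59 ± 0.26, and none passed over all genes or when adjusted over the list alone. The histone list had a camera adjusted p = 0.00011, an adjusted p = 0.49 with an estimated correlation and a fry adjusted p = 0.26.

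Amino acid biosynthesis genes had a list median of -0.21, with 39 of 48 tested members below 0 in the mean (camera adjusted p = 0.00027, and adjusted p = 0.42 with an estimated correlation). No member passed over all genes or when adjusted over the list alone, and fry gave an adjusted p = 0.15. The lysine genes LYS12 and LYS20 were at -0.56 ± 0.14 (SE, n = 4) and -0.56 ± 0.16. The sulfate assimilation genes MET14 and MET3 went the other way, at 0.86 ± 0.17 and 0.64 ± 0.17. Glycolysis genes had a list median of -0.22, with 15 of 19 members below 0 in the mean and array medians of -0.41, -0.33, -0.17 and 0.23 (camera adjusted p = 0.019, and adjusted p = 0.62 with an estimated correlation). None passed over all genes or when adjusted over the list alone. FBA1, the aldolase, was at -0.45 ± 0.20, and PFK1, of phosphofructokinase, was at -0.36 ± 0.14. TDH1 was at -0.42 ± 0.22 and stood apart on array 2, at -1.12. The glycolysis call was lost without array 1 (median -0.17, adjusted p = 0.10), without array 2 (median -0.15, adjusted p = 0.31), without array 3 (median -0.20, adjusted p = 0.056), without centring (0.053), with arrays scaled to a common spread (0.054), with quantile normalization (0.058) and by fry (0.49). Without array 4, the only one above 0, the list lay lower (median -0.39, adjusted p = 0.00027).

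**Figure D2:**
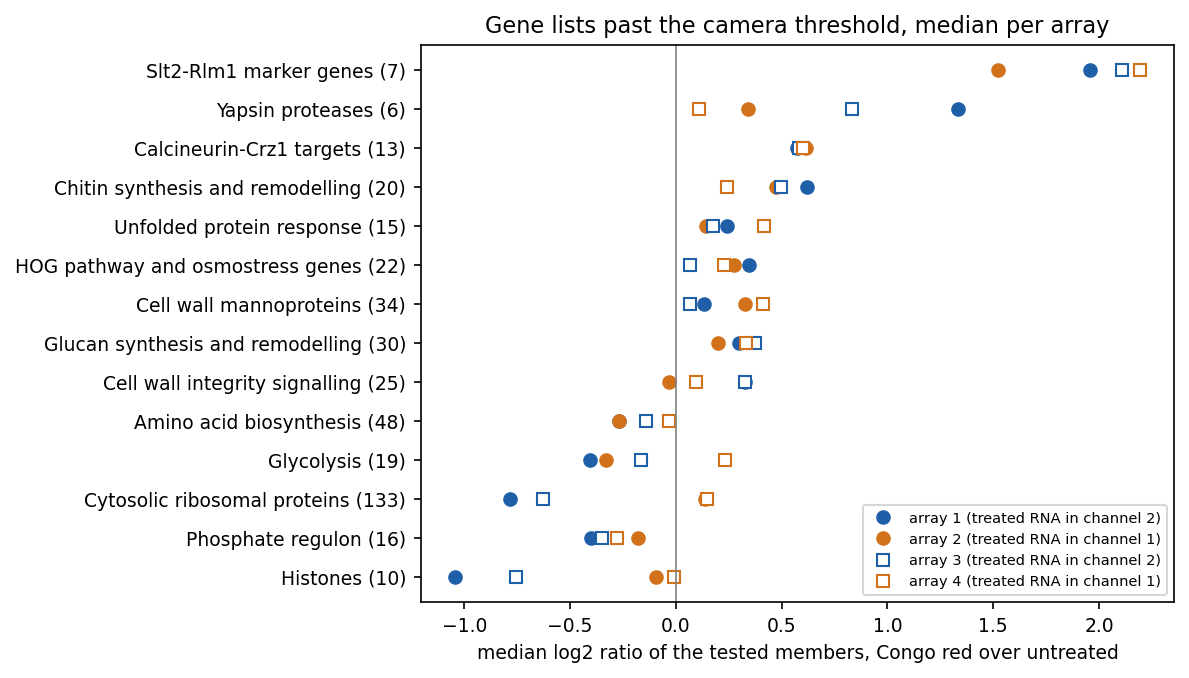
Median log2 ratio of the tested members of 14 gene lists on each array (horizontal axis), with the list and its number of tested members on the vertical axis. Filled symbols are arrays 1 and 2, open symbols arrays 3 and 4. The ribosomal protein list lies at -0.78 and -0.63 on arrays 1 and 3 and at 0.14 and 0.15 on arrays 2 and 4, while the Slt2-Rlm1 marker list lies between 1.52 and 2.19.

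The other 14 of the 28 lists did not pass the camera threshold. General stress genes under Msn2/4 had a median of 0.09 (camera adjusted p = 0.37), none of 45 passed over all genes, and 2 passed when adjusted over the list alone. These were HSP12, of a small membrane-bound stress protein, at 1.29 ± 0.18 (SE, n = 4) and TPS2, of trehalose synthesis, at 1.10 ± 0.16, which stood apart on array 2 at 1.504. Heat shock chaperones had a median of -0.05 (camera adjusted p = 0.32), with HSP26 at -0.81 ± 0.17. Protein mannosylation genes had a median of -0.02 and a mean of 0.10, and the test pointed down (camera adjusted p = 0.86), although the mannosyltransferase gene KTR2 was at 1.65 ± 0.33. None of the members of either list passed over all genes or when adjusted over the list alone.

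Lists of growth and metabolism gave medians of -0.04 for ribosome biogenesis (camera adjusted p = 0.19), 0.02 for the TCA cycle and respiratory chain (0.37), -0.07 for ergosterol synthesis (0.37) and -0.09 for the iron regulon (0.27). Without array 1 the TCA cycle list passed, with a median of 0.14 (adjusted p = 0.035), and without array 4 its test pointed down. Cell cycle lists gave medians of -0.26 for G2/M genes (camera adjusted p = 0.064), -0.04 for G1/S genes (0.56) and 0.09 for daughter-specific cell separation genes (0.53). The G1/S list had a mean of 0.15 where its median and test lay below 0. The G2/M list passed without array 1 (median -0.30, adjusted p = 0.048), with centring along the spot order (median -0.24, adjusted p = 0.034) and without spot pairs more than 1 apart (median -0.25, adjusted p = 0.0498). Lists of mating and cell type gave medians of 0.02 for pheromone response and a-cell genes (camera adjusted p = 0.37), -0.0048 for alpha-cell genes (0.79, with a mean of 0.13) and 0.03 for meiosis and sporulation genes (0.71). No member of these 10 lists passed over all genes or when adjusted over the list alone.

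Both RNAs of each array come from cells with the deletions of BY4741, so the ratios of the deleted genes carry no check of the labels. HIS3 was at -0.50 ± 0.21 (SE, n = 4), LEU2 at -0.24 ± 0.14 and MET17 at -0.13 ± 0.25, and URA3 had values on arrays 3 and 4 only, at 1.46 and -1.29. The list had a camera adjusted p = 0.092 and a fry adjusted p = 0.016, and none of its 3 tested members passed over all genes or when adjusted over the list alone.

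The channel assignments were compared because the direction of the deposited ratios is unstated. Over genes, which are not independent replicates, Pearson's r between arrays of opposite assignment averaged -0.04, from -0.06 to -0.02. This lies within 0.3 of 0, where the rule fixed for it leaves open whether the values run by treatment or by channel. Spearman's rho was 0.60 between arrays 1 and 3, 0.20 between arrays 2 and 4, and between -0.12 and -0.06 for opposite assignments. The values were used as deposited, because the 8 marker genes, known from background to be induced by Congo red, were above 0 on every array with a value. Their mean over the 7 tested was 2.01 (95% confidence interval 1.47 to 2.54). That interval takes the genes as replicates, although they belong to 1 route and were measured on the same arrays. It does not measure the spread between arrays. Of 5124 genes measured on all arrays, 18 were at least 2-fold higher on all 4, against 1.64 if the array pairs were independent, and 2 were at least 2-fold lower, against 0.19. The pattern of 2-fold higher on arrays 1 and 3 and 2-fold lower on arrays 2 and 4 held for 2 genes, against 0.93, and its opposite for 0 genes, against 0.34. With the sign of arrays 2 and 4 turned, limma called 0 genes (671 at an unadjusted p under 0.05) and the marker mean was 0.10. That marker mean follows from the markers being above 0 on every array, so it adds no further support. A channel term passed the limma threshold for 0 of 5489 genes, but 912 had an unadjusted p under 0.05, where chance alone gives 274 and the treatment had 726 in the same fit.

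**Figure D3:**
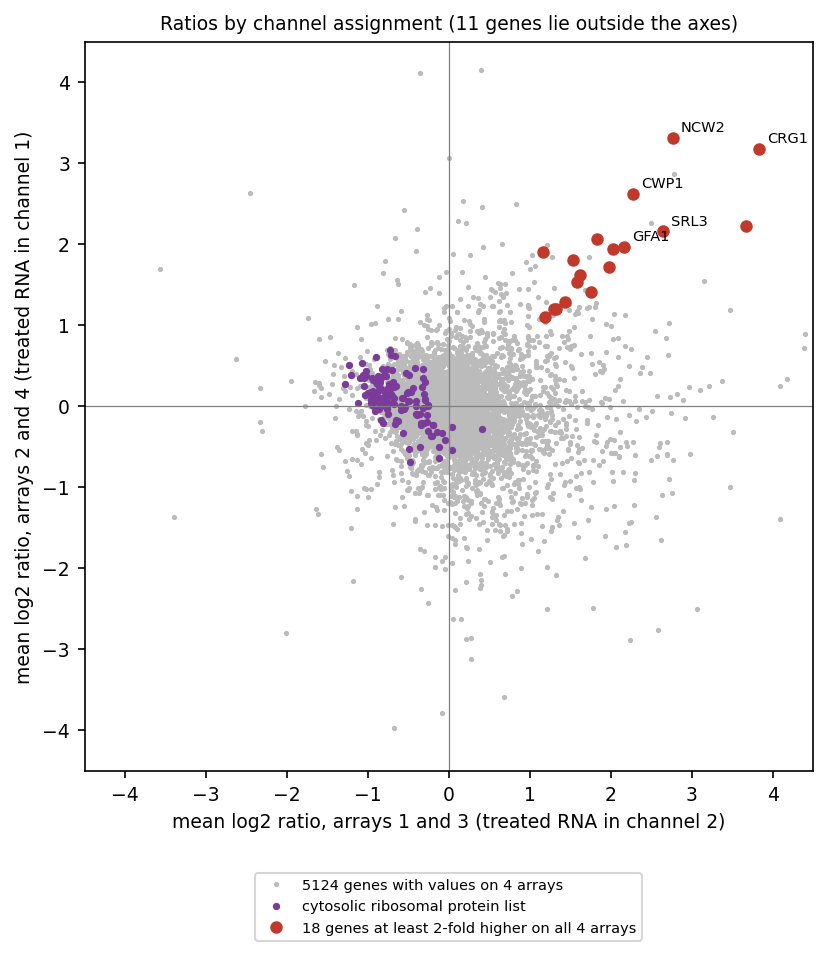
Mean log2 ratio of Congo red over untreated on arrays 1 and 3 (horizontal axis) against arrays 2 and 4 (vertical axis), with 1 point per gene for 5124 genes, 11 of which lie outside the axes. Red marks the 18 genes at least 2-fold higher on all 4 arrays and violet the ribosomal protein list, most of which lies left of 0 on the horizontal axis and around 0 on the vertical axis.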

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

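Of the tests in this part, those on the ribosomal protein genes were chosen only after the result was seen.

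The ribosomal protein genes differed between the channel assignments by -0.85 in the list median (arrays 1 and 3 minus arrays 2 and 4), with opposite signs in the pairs. No p-value was computed for that difference. Arrays of the same assignment differed by at most 0.16. A treatment effect of 1 size on all arrays does not describe these medians by itself. The list was flagged for the same medians, so this is no separate test of such an effect, which stays open beside another cause. A channel effect left in the deposited ratios stays open. Over 5124 genes, the means of the assignments had a Spearman's rho of -0.13 (95% bootstrap interval -0.16 to -0.10), below 0 as an effect that changes sign with the channel needs. Values below 0 had already been seen between single arrays, so this does not count as evidence for it. Separate cultures behind the assignments stay open, since 0 labels name the cultures, and so does a treatment response that differed between them.

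Ribosome biogenesis genes differed by 0.17 between the assignments and the TCA cycle and respiratory chain list by -0.40, both with opposite signs in the pairs and with the difference untested. The histone and yapsin lists kept 1 sign and were not flagged, yet their medians lay about as far apart as those of the ribosomal list. Histones were at -1.04 and -0.75 on arrays 1 and 3 and at -0.09 and -0.01 on arrays 2 and 4. Yapsins were at 1.33 and 0.83 against 0.34 and 0.11. These differences were not tested either. Single arrays stood far from the others in 9 of 109 values examined, and chance alone gives about 1 in 20. On array 2 these were GFA1 at 1.77, SVS1 at 0.76, TDH1 at -1.12, TPS2 at 1.504, the heat shock chaperone list at -0.27 and the daughter-specific cell separation list at -0.26. On array 4 they were CWP1 at 3.06 and GPD1 at 0.51, and on array 1 the G1/S list at -0.14.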

How the results depend on the processing

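The alternatives that left out spot pairs, values at the upper limit or RPP1, centred along the spot order, turned arrays 2 and 4 or ran camera itself with the preset correlation were chosen after the data were seen. The 5 higher genes became 0 with arrays scaled to a common spread, with quantile normalization, a channel term, either pair averaging, a test against a fold change of 1.5, centring within runs of 400 spots, and arrays 2 and 4 turned. The count was 3 spots (of CRG1 and NCW2) when spots were tested alone. It was 11 genes without spot pairs more than 1 apart, where fewer genes were tested (4896) and 5 of the 11 were the main 5. Leaving out each array gave 0 to 0. Without centring it was 6, of which 4 were shared: PST1 lost its call, and CWP1 and YPL088W came in. Other settings gave 5 to 7, and lower genes stayed at 0 in all settings run. With an estimated correlation 0 lists were higher and 0 lower, in place of 9 and 5. Camera itself with the preset correlation on the same genes gave 8 and 5, so the loss came with the estimate, which in limma also lowers the degrees of freedom. The estimated correlation lay below the preset 0.01 for the calcineurin (-0.051), chitin (-0.037), unfolded protein (-0.031), HOG (-0.011) and glucan (-0.010) lists. For these lists the values argue against correlation between genes as the cause of the loss. For the other called lists it lay above 0.01, up to 0.93 for histones. By fry 6 were higher, all among the 9, and 2 lower, the phosphate regulon and the deleted genes. Treated and untreated cells carry the same deletions, and camera did not call the deleted genes (adjusted p = 0.092). A fry call alone is therefore weak evidence of a response. Leaving out arrays gave 6 to 10 higher and 4 to 5 lower lists. The test direction turned for protein mannosylation without centring (median 0.040), with scaling (-0.019), quantile normalization (-0.013) and fry (-0.032), and also without array 1 (-0.0045), array 2 (-0.021) or array 3 (0.0076), but not without array 4 (-0.11). It turned without array 1 for G1/S (medians over left-out arrays -0.081 to -0.018) and meiosis (-0.27 to 0.19), and without array 4 for TCA (-0.10 to 0.14) and alpha-cell genes (-0.16 to 0.24). MET17 turned to 0.015 without array 2 (lowest -0.38) and 0.0033 with run centring. Fewer arrays were fitted in the left-out settings, and for the others the cause was not tested. Signal over background was not used here, so its limit is unknown.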

Other observations

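Of the tests in this part, the count over sign patterns was chosen only after the result was seen, and the genes named in the next paragraph were chosen after their values were seen.

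Beyond the genes described above, several others were at least 2-fold higher on all 4 arrays without passing the limma threshold. MCH5, a riboflavin transporter of the plasma membrane, was at 1.85 ± 0.16 (SE, n = 4, limma adjusted p = 0.062). DFG5, a membrane protein needed for wall assembly, was at 1.67 ± 0.20, and PUN1, a plasma membrane protein, at 1.53 ± 0.22. MSB3, a GTPase-activating protein for Rab proteins in secretion, was at 1.62 ± 0.21. FLC1, a membrane protein of flavin transport, was at 1.26 ± 0.13, the vacuolar protease gene PRB1 at 1.25 ± 0.13 and RTS3 at 1.14 ± 0.13. YPL088W and YNL058C were at 2.94 ± 0.39 and 1.58 ± 0.18. The limma adjusted p of these genes other than MCH5 ran from 0.12 for PRB1 to 0.18 for PUN1. On the lower side, the vacuolar aminopeptidase gene APE1 and ESC8 were at least 2-fold lower on all 4 arrays, at -2.40 ± 0.49 (limma adjusted p = 0.35) and -2.38 ± 0.52 (limma adjusted p = 0.39), with single arrays down to -4.18 and -4.01.

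MET3, MET14 and MET16 of sulfate assimilation were above 0 on all arrays, at 0.64 ± 0.17, 0.86 ± 0.17 and 0.64 ± 0.21 (SE, n = 4). The hypothesis that sulfate and methionine genes shift as a group was tested on 18 genes of that kind not looked at singly. The prediction of a camera p under 0.05 was not met: their median was 0.07, 8 were below 0, and the camera p was 0.33 with the test pointing down. Members were also looked at after their values were seen. SAM1, SAM2, SAM3 and MHT1 were above 0 on 0 of 4 arrays, MET10 on 1, and MET5, MET8 and SUL1 on 3. The list is thus mixed, and the test does not show that the sulfate assimilation genes alone did not shift.

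The phosphate regulon list may rest on signal shared between the acid phosphatase genes. Without PHO5, PHO11 and PHO12, the 13 remaining genes had a median of -0.22 with 8 below 0, and the camera p was 0.12. This does not decide it: the prediction was a p of 0.05 or more, but a p that misses the threshold does not show that the remaining genes did not shift, and 13 genes are few. A lower phosphate response in treated cells stays open.

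Ratios varied along the spot order. Medians of 32 runs of 400 spots had an SD of 0.18, 0.19, 0.19 and 0.13 on arrays 1 to 4, and the highest of 1000 shuffles of the spot pairs on array 4 was 0.045, so a trend with position on the array may be present. The spot order is taken here for position, as no layout was used. Centring within runs moved the means of all 5 of the 5 called genes by less than 2 standard errors, at most by 0.11. The highest run medians were 0.31, 0.31, 0.38 and 0.19 on arrays 1 to 4. Shifts of that size could not have lowered 3 of the 5 means by 2 standard errors, so this test cannot decide on position. They are small beside the ratios of the 5 genes. As the calls ended, the standard error of NCW2 went from 0.18 to 0.23 and that of SRL3 from 0.17 to 0.20. The NCW2 mean also fell to 2.93, and these parts were not separated. Unadjusted limma p became 7.59e-05 for NCW2 and 8.42e-05 for SRL3. With fewer genes at the top ranks, the limma adjusted p became 0.060 for CRG1, GFA1 and PST1 and 0.077 for NCW2 and SRL3.

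The 4 arrays allow 8 sign patterns, and 1 of these, the real one, gave as many as 5 genes, while the highest of the others gave 0. The patterns are too few for a share under 0.05.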
